A study of Mus musculus with 8 samples.

How the data were processed

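Macrophages were sorted with a Cd11b-PE antibody from mammary tissue digested with collagenase. The donors carried the MMTV-iFGFR1 transgene or were littermates without it, after 48 hours or 4 weeks of dimerizer. RNA of 3 mice was pooled per array, isolated with a PicoPure kit and amplified in a two-cycle protocol before hybridisation to Affymetrix whole-genome arrays of the mouse. The 8 arrays fall into 4 groups of 2 pools: control and transgenic at 48 hours, control and transgenic at 4 weeks. Amplification in 2 cycles shortens transcripts, so a probe set far from the 3' end can lose signal with RNA quality.

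The deposited values are signal intensity per probe set, made by the authors with MAS5 per the submitters' processing notes, which give no version. The values are linear, with a lowest signal of 0.3 and a highest of 159546.7, and each array was scaled by the authors to one target: the mean without the lowest and highest 2% of probe sets was 500 on all 8 arrays. No detection calls came with the values, so low signals could not be told from absence. For arrays, depth is not counted in reads, and the number of arrays limits the precision.

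Of 45101 probe sets, 64 were array controls, 34945 carried 1 gene symbol, 932 several and 9160 none. Probe sets with 1 symbol were used, which leaves out genes that have no probe set of their own. Signals were turned into log2(signal + 30.8), where 30.8 is the 25th percentile of all values in the table, with no further scaling between arrays. Log2 differences are on this scale, so they are smaller than those of raw signals for dim genes. A probe set was kept where its signal lay above its array's median on at least 2 arrays, and of a gene's kept probe sets the one with the highest mean log2 value over all arrays was used. This gave 13083 genes. Signals in the text are means and SD of the linear MAS5 values of 2 pools.

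Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend in the prior variance), with a mean for each of the 4 groups and 1 estimate of the spread shared by the groups. The fit left 4 residual degrees of freedom, and the prior added a median of 6.33. The contrasts were transgenic minus control at 48 hours and at 4 weeks, the difference between these, and 4 weeks minus 48 hours in control and in transgenic pools. The genotype difference over both times was fitted with time as a covariate. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes of a contrast, with 0.05 as the threshold. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

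The 32 gene lists, covering macrophage states, other leukocytes, mammary epithelium, stroma and signalling pathways, were written from textbook knowledge before the data were examined, as were the contrasts, the tests, the rule for named genes and the alternatives below except those named as added later. Each list was tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the 32 lists of a contrast. Camera with the correlation estimated from the residuals and fry were run beside it. For each list, the members past the threshold were also counted with p adjusted over the list alone. The genes named in the text are, for each genotype contrast, the 10 highest and 10 lowest log2 differences past the threshold with both transgenic pools on one side of both control pools, filled up with the smallest p-values of that direction where fewer passed, and for the other contrasts the 5 in each direction past the threshold. Up to 4 members of each list with the smallest p and a fixed set of macrophage and chemokine genes could be named too. Some genes the rule allows were left out of the text for length.

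RNA quality was read per array from the 3', middle and 5' probe sets of the beta-actin and Gapdh controls and compared between genotypes with an exact permutation test over 4 and 4 arrays, where the smallest two-sided p is 0.0286. Differences between transgenic and control pools of the same pool number were computed beside each list's median.

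The alternatives were quantile normalization, no offset, an offset at the median of 108.1, no filter, a filter at the 75th percentile, all probe sets tested separately, no trend in the prior variance, array weights, the pool number as a block, the 4 arrays of a time alone, other thresholds, and leaving out each of the 8 pools in turn. An array's actin ratio as a covariate and, for the correlation of the genotype differences, each pool left out and the pool number as a block were added after seeing the data. The pipeline was tested on simulated data of the 48 hours contrast, with 10 runs of 200 changed genes among 13083. It recovered 7.49% of 2-fold, 52.9% of 4-fold and 78.9% of 8-fold changes with a mean of 6.3 false calls. Camera with the preset correlation called a shifted list of 15 genes in 10 of 10 runs and an unshifted one in 0 of 10. The simulated genes varied independently of each other, so these runs cannot show how often camera falsely calls a list of correlated genes.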

Results

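The data describe gene expression in macrophages of the mouse mammary gland early and late after fibroblast growth factor receptor 1 (FGFR1) was switched on in the gland's epithelium. MMTV-iFGFR1 mice carry an inducible form of the receptor under the mouse mammary tumour virus promoter, which is active in mammary epithelial cells. A synthetic dimerizer brings the receptor molecules together and starts their signal. Transgenic females and their littermates without the transgene, all on the FVB background and 6 weeks old at the start, received the dimerizer for 48 hours or for 4 weeks. The littermates therefore give the background of age and dimerizer at each time. Mammary cells stained for Cd11b, a surface protein of macrophages that neutrophils, monocytes, NK cells and some dendritic cells also carry, were sorted. RNA of 3 mice was pooled for each array, and each of the 4 groups had 2 pools, so that 8 Affymetrix arrays of the mouse genome were compared. One label conflicts with the others: the description of transgenic 4 weeks pool 2 speaks of mice without the transgene, while its title, source and genotype name the transgenic line, and it was used as transgenic.

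The median signal of an array lay between 96.2 and 126.7 units, and the scaled mean was 500 on each. Csf1r, the receptor for the main macrophage growth factor, gave a signal of 68311 to 93065 on the 8 arrays. Adgre1, an adhesion receptor typical of mouse macrophages, gave 9842 to 14627. Itgam, the gene of Cd11b itself, was dimmer on these arrays, at 46.8 on control 4 weeks pool 2 and 184 to 545 on the others. Fgfr1 gave 1132 ± 0.919 in control and 1192 ± 59.5 (SD, n = 2 pools) in transgenic pools at 48 hours, and its log2 difference was 0.07 (SE 0.43). At 4 weeks the log2 difference was 0.28 (SE 0.43) and −0.53 without control 4 weeks pool 2. The transgene is driven in epithelium, so the Fgfr1 signal of sorted macrophages does not check it. Across genes, the correlation between arrays ran from 0.919 to 0.961, with a mean of 0.941 within groups and 0.941 between groups. Genes are not independent replicates, and no p-value was attached to it.

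RNA quality was read from the ratio of 3' to 5' signal of the beta-actin control, which grows as RNA is shortened. The ratio was 37.0-fold on control 4 weeks pool 2 and 6.84- to 13.9-fold on the other 7 arrays. The Gapdh ratio was 12.1-fold on that pool. Over all arrays the log2 actin ratio was 3.06 ± 0.32 in transgenic and 3.88 ± 0.95 (SD, n = 4 arrays each) in control pools, exact permutation p = 0.143, two-sided. The difference for Gapdh was −0.20, exact permutation p = 0.371. The number of arrays limits the precision of every comparison. Each group has 2 pools, so a fit without 1 of them rests on the other alone for that group. Without control 4 weeks pool 1 the only 4 weeks control is the pool with the ratio of 37.0-fold. The p-values of limma and of the permutation tests measure the spread between pools of 3 mice, not between mice. Camera compares a list's genes with all other genes. With its preset correlation its p-values assume nearly independent genes and do not measure how well a list's change repeats between pools. With an estimated correlation 0 lists were called in any comparison.

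**Figure D1:**
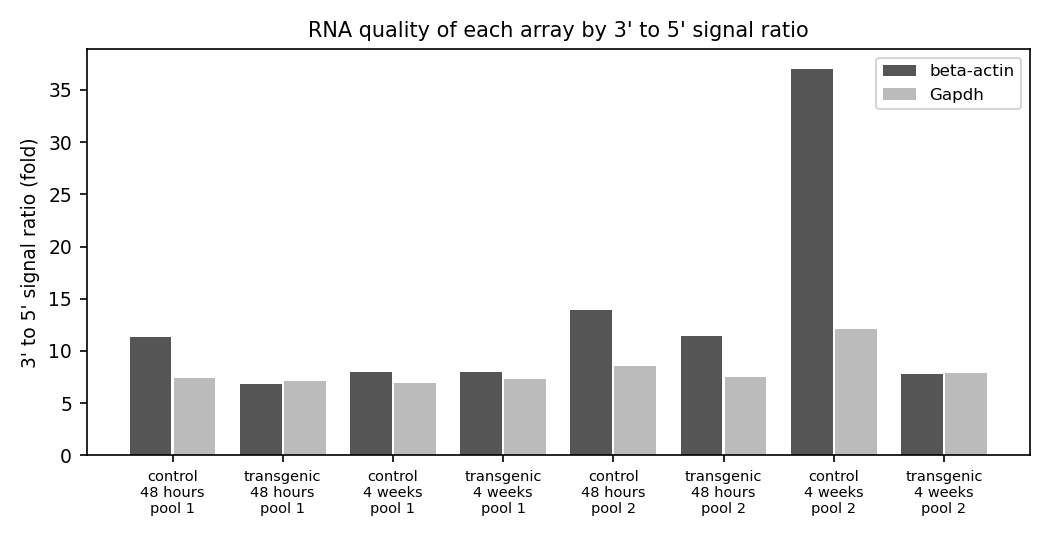
Ratio of 3' to 5' signal (fold, linear axis from 0) of the beta-actin and Gapdh controls on each of the 8 arrays, 1 bar per array. Control 4 weeks pool 2 stands at 37.0 for beta-actin and 12.1 for Gapdh, above the other 7 arrays in both.

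The comparison at 48 hours asked which macrophage transcripts differ soon after the receptor is activated in the epithelium. Genes of luminal epithelial cells, the cells that line the ducts, had a higher signal in the transgenic pools. Krt8, a keratin of simple epithelia, had a signal of 664 ± 54.9 in control and 3219 ± 668 (SD, n = 2) in transgenic pools, a log2 difference of 2.21 (SE 0.35). The Krt8 gene lies on chromosome 15 at 101996711 to 102004342 of the mouse genome build GRCm38. Epcam, an epithelial adhesion protein, gave 108 ± 58.6 and 662 ± 53.0 (SD, n = 2), a log2 difference of 2.38 (SE 0.48). Wfdc18, a secreted protein of the mammary epithelium, gave 2107 ± 174 and 5522 ± 507, and Pgr, the progesterone receptor, 111 ± 29.3 and 522 ± 143 (SD, n = 2). Of the 15 measured luminal genes, 12 had a positive difference, 8 passed with a higher signal when p was adjusted over the list alone, and 0 passed over all genes tested in limma. The median log2 difference of the list was 1.26, adjusted p = 2.35e-09 in camera with its preset correlation. It had adjusted p = 0.516 with an estimated correlation. Between the pools numbered 1 the median was 1.06 and between those numbered 2 it was 1.20. Relative to the mean of all 8 arrays, the luminal list stood at −0.71 and −0.63 in the control 48 hours pools, the lowest of the 8, and at 0.15 and 0.42 in the transgenic ones.

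Milk protein genes, also products of the luminal epithelium, had a median log2 difference of 0.93 at 48 hours, adjusted p = 0.035, and adjusted p = 0.853 with an estimated correlation. Csn3, which encodes kappa-casein, gave 914 ± 83.9 in control and 6573 ± 604 (SD, n = 2) in transgenic pools, a log2 difference of 2.80 (SE 0.49). Its gene lies on chromosome 5 at 87925579 to 87932550. Lalba, alpha-lactalbumin, had a log2 difference of 1.96 (SE 0.51). These were the 2 of 7 milk protein genes that passed adjusted over the list alone, and 0 passed over all genes tested. The list's call depended on single pools: its median was 0.33 (adjusted p = 0.273) without control 48 hours pool 1, 0.52 (adjusted p = 0.0545) without transgenic 48 hours pool 1 and 1.25 (adjusted p = 0.0736) without transgenic 48 hours pool 2. Without control 48 hours pool 2 it was 1.54 (adjusted p = 0.0367), and with each array's actin ratio as a covariate it was 0.07 (adjusted p = 0.179). It was 1.75 between the pools numbered 1 and 0.06 between those numbered 2. With all arrays Csn3 had limma's adjusted p = 0.853, and with the 4 arrays of 48 hours fitted alone 0.0098. Its log2 difference was 2.80 in that fit too, and without either control 4 weeks pool. Such fits change only the shared estimate of its spread, which the control 4 weeks pools widen with signals of 6631 and 1660.

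**Figure D2:**
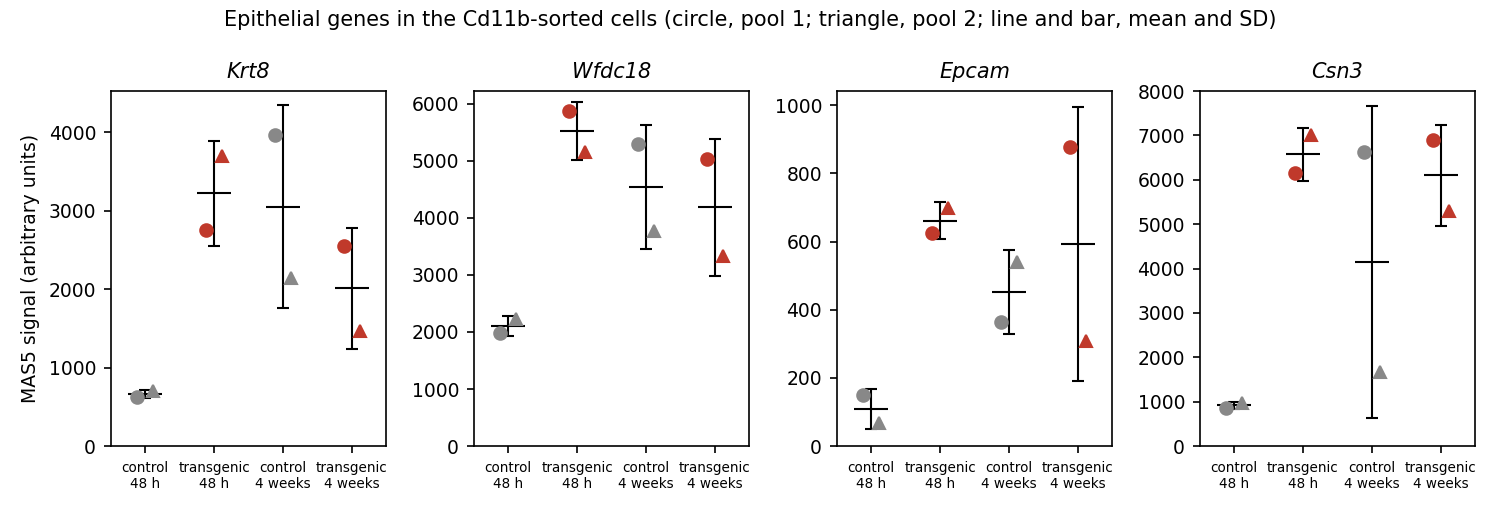
MAS5 signal (linear axis from 0) of Krt8, Wfdc18, Epcam and Csn3 in the 4 groups, with circles for pool 1, triangles for pool 2, grey for control and red for transgenic pools, and a line and bar for the mean and SD of 2 pools. At 48 hours both transgenic pools lie above both control pools for each gene, as for Krt8 with means of 3219 and 664.

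Inflammatory genes had lower signals in the transgenic pools at 48 hours. Of 16 measured inflammatory cytokines and NF-kB targets, 15 had a negative difference and 0 passed, adjusted over the list alone or over all genes. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, gave 9141 ± 620 in control and 5645 ± 1141 (SD, n = 2) in transgenic pools. Il1rn, the interleukin 1 receptor antagonist, gave 3144 ± 863 and 1695 ± 569 (SD, n = 2), and Il12b, a subunit of interleukins 12 and 23, had a log2 difference of −1.37 (SE 0.56). The list's median was −0.41, adjusted p = 3.18e-05, and adjusted p = 0.853 with an estimated correlation. It was −0.57 between the pools numbered 1, −0.32 between those numbered 2, and −0.69 (adjusted p = 5.29e-05) without control 48 hours pool 2. Genes of dendritic cells, the antigen-presenting relatives of macrophages, had a median of −0.41 with 10 of 12 negative, adjusted p = 0.035, and adjusted p = 0.853 with an estimated correlation. The dendritic median was −0.13 between the pools numbered 1 and −0.18 between those numbered 2. Itgae, an integrin of tissue dendritic and T cells, had a log2 difference of −0.70 (SE 0.35). None of the dendritic genes passed, and the list's call was lost without control 48 hours pool 1 (median −0.39, adjusted p = 0.362) or transgenic 48 hours pool 2 (median −0.16, adjusted p = 0.573), and the median was −0.63 (adjusted p = 0.0367) without control 48 hours pool 2. With the actin ratio as a covariate the dendritic median was −0.22 (adjusted p = 0.17).

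All 16 measured genes of oxidative phosphorylation had a positive difference at 48 hours, with a median of 0.29, adjusted p = 0.000738, and adjusted p = 0.853 with an estimated correlation. Ndufb5, a subunit of respiratory complex I, had a log2 difference of 0.42 (SE 0.22), and Cox5a, a subunit of cytochrome oxidase, 0.37 (SE 0.21). The median was 0.45 between the pools numbered 1, 0.12 between those numbered 2, and 0.19 (adjusted p = 0.0545) without transgenic 48 hours pool 1. Fibroblast genes were higher with 12 of 13 positive, a median of 0.43 and adjusted p = 0.00421, and adjusted p = 0.853 with an estimated correlation. Dpt, a protein of the dermal and stromal matrix, gave 1632 ± 174 in control and 2619 ± 512 (SD, n = 2) in transgenic pools. The fibroblast median was 0.93 between the pools numbered 1 and −0.18 between those numbered 2, and it turned to −0.11 (adjusted p = 0.57) without control 48 hours pool 1 and was 0.94 (adjusted p = 1.56e-08) without control 48 hours pool 2. In both lists 0 genes passed, adjusted over the list alone or over all genes.

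Among single genes outside these lists, Arg1, the arginase of alternatively activated macrophages, was near the floor in control pools at 8.85 ± 4.17 and gave 109 ± 38.1 (SD, n = 2) in transgenic pools at 48 hours, so the size of its difference depends on the offset. The list of alternative activation had 9 of 15 negative and a median of −0.16, adjusted p = 0.814. Vegfa, an angiogenic growth factor, had a log2 difference of 1.20 (SE 0.54), in a list of growth and angiogenic factors with 7 of 13 negative and a median of −0.12, adjusted p = 0.918, and Cx3cr1, the fractalkine receptor of monocytes and macrophages, −0.66 (SE 0.29). The smallest p-values with higher signal included Rce1, a protease that processes prenylated proteins, at a log2 difference of 1.86 (SE 0.34), Ptn, the growth factor pleiotrophin, at 1.68 (SE 0.31) and Mlph, an adaptor of melanosome transport, at 2.09 (SE 0.45). Those with lower signal included Sirt6, a chromatin deacetylase, at −2.63 (SE 0.54), Krt78 at −2.45 (SE 0.51), the metalloprotease gene Adamdec1 at −2.12 (SE 0.45) and Sox10, a transcription factor of neural crest and glia, at −1.43 (SE 0.36). The Sirt6 signal was 372 ± 100 (SD, n = 2) in control and 34.9 ± 20.9 in transgenic pools, and several of the genes with lower signal were as dim. In limma, 0 of 13083 genes passed an adjusted p of 0.05 at 48 hours, and the lowest adjusted p was 0.853, shared by Krt8 and others. At an unadjusted p under 0.05 there were 535 genes, 276 higher and 259 lower, against 654 by chance. On simulated data of this design, limma recovered 7.49% of 2-fold, 52.9% of 4-fold and 78.9% of 8-fold changes, so most small differences would have been missed.

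The comparison at 4 weeks asked which transcripts differ after sustained activation. Genes of the interferon response, the antiviral program, had lower signals in transgenic pools. Rsad2, which encodes the antiviral enzyme viperin, gave 16120 ± 3273 in control and 5971 ± 549 (SD, n = 2) in transgenic pools, a log2 difference of −1.42 (SE 0.27). The Rsad2 gene lies on chromosome 12 at 26442743 to 26456452. Oas2, a sensor of double-stranded RNA, gave 4701 ± 294 and 2118 ± 787 (SD, n = 2), and Mx1, an antiviral GTPase, had a log2 difference of −1.50 (SE 0.38). Of 17 measured interferon genes, 16 had a negative difference, 8 passed with a lower signal adjusted over the list alone, and 0 passed over all genes in limma. The list's median was −1.19, adjusted p = 2.98e-13, and adjusted p = 0.283 with an estimated correlation. It was −1.59 between the pools numbered 1 and −0.87 between those numbered 2. The call held in each of the 8 fits without 1 pool. Leaving out a 48 hours pool cannot move this median, so only the fits without a 4 weeks pool test it. Without control 4 weeks pool 1 the median was −0.73. That fit has pool 2, the array with the actin ratio of 37.0-fold, as its only 4 weeks control. In control 4 weeks pool 1 the list stood 1.13 above the mean of all arrays, against 0.16 in control 4 weeks pool 2 and −0.27 and −0.64 in the transgenic pools. At 48 hours the interferon genes stood at −0.39 and 0.19 in control and −0.18 and 0.00 in transgenic pools.

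**Figure D3:**
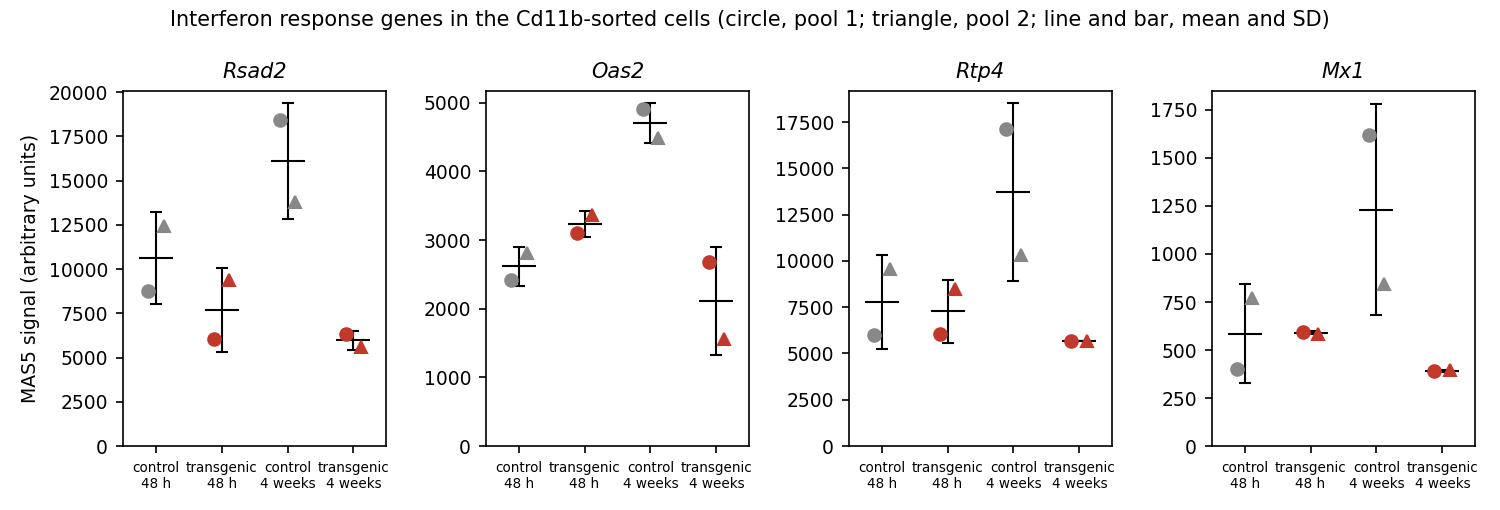
MAS5 signal (linear axis from 0) of Rsad2, Oas2, Rtp4 and Mx1 in the 4 groups, with circles for pool 1, triangles for pool 2, grey for control and red for transgenic pools, and a line and bar for the mean and SD of 2 pools. At 4 weeks both transgenic pools lie below both control pools for each gene, as for Rsad2 with means of 5971 and 16120.

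Neutrophil genes also had lower signals in transgenic pools at 4 weeks, with 14 of 15 negative and a median of −0.56, adjusted p = 0.000165, and adjusted p = 0.283 with an estimated correlation. S100a8, part of the granulocyte protein calprotectin, had a log2 difference of −1.76 (SE 0.47), and its partner S100a9 −1.54 (SE 0.46). Ltf, lactoferrin, which granulocytes and the mammary epithelium both make, gave 1032 ± 22.5 in control and 387 ± 28.8 (SD, n = 2) in transgenic pools. These 3 genes passed adjusted over the list alone, and 0 passed over all genes. The list's median was −0.34 between the 4 weeks pools numbered 1 and −1.13 between those numbered 2. It was −0.14 (adjusted p = 0.0273) without control 4 weeks pool 2, the pool with the actin ratio of 37.0-fold, and −1.28 (adjusted p = 8.65e-06) without control 4 weeks pool 1. With the actin ratio as a covariate it was −0.20 (adjusted p = 0.0134). The neutrophil list stood 0.69 above the mean of all arrays in control 4 weeks pool 2 and −0.08 in pool 1. At 48 hours the Ltf signal was the other way, at 304 ± 38.5 in control and 743 ± 174 (SD, n = 2) in transgenic pools, as was that of Lcn2, the siderophore-binding lipocalin 2, at 265 ± 5.51 and 807 ± 151 (SD, n = 2). Those 2 genes passed with a higher signal at 48 hours adjusted over the neutrophil list alone and 0 passed over all genes, while the list had 11 of 15 negative and a median of −0.15, adjusted p = 0.37.

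Matrix remodelling genes had higher signals in transgenic pools at 4 weeks. Fn1, which encodes fibronectin, gave 12140 ± 681 in control and 22890 ± 556 (SD, n = 2) in transgenic pools, a log2 difference of 0.91 (SE 0.24). Mmp12, the macrophage elastase, gave 184 ± 24.7 and 511 ± 166 (SD, n = 2). Adam8, a membrane protease of leukocytes, had a log2 difference of 0.79 (SE 0.33). Of 18 measured matrix genes, 13 had a positive difference and 0 passed, adjusted over the list alone or over all genes. The median was 0.49, adjusted p = 0.00137, and adjusted p = 0.283 with an estimated correlation. The fry test, which asks whether a list's genes move one way on balance and does not compare them with other genes, gave the list an adjusted p = 0.0154. The median was 0.60 between the pools numbered 1, 0.46 between those numbered 2, and 0.31 (adjusted p = 0.0216) without control 4 weeks pool 1.

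Genes of MHC class II presentation, by which macrophages show peptides to T cells, were higher in transgenic pools at 4 weeks with 10 of 10 positive and a median of 0.61, adjusted p = 0.000165, and adjusted p = 0.45 with an estimated correlation. Cd74, the invariant chain, gave 18620 ± 4136 in control and 32680 ± 3047 (SD, n = 2) in transgenic pools. The call was lost without control 4 weeks pool 1 (median 0.32, adjusted p = 0.0954) or transgenic 4 weeks pool 2 (0.30, adjusted p = 0.124), and the median was 0.55 within each pool number. Growth and angiogenic factors had 12 of 13 positive and a median of 0.58, adjusted p = 0.000343, and adjusted p = 0.283 with an estimated correlation. Vegfa gave 237 ± 150 in control and 785 ± 243 (SD, n = 2) in transgenic pools, Wnt7b, a WNT ligand, had a log2 difference of 1.35 (SE 0.54), and Hgf, hepatocyte growth factor, 0.77 (SE 0.31). This call was lost without control 4 weeks pool 1 (median 0.32, adjusted p = 0.164) or transgenic 4 weeks pool 2 (0.18, adjusted p = 0.0858), and the median was 0.87 (adjusted p = 6.16e-05) without transgenic 4 weeks pool 1. It was 0.50 between the pools numbered 1 and 0.69 between those numbered 2. Inflammatory genes had 12 of 16 positive and a median of 0.34, adjusted p = 0.00521, and adjusted p = 0.515 with an estimated correlation. Il1b, a main cytokine of activated macrophages, gave 11960 ± 3301 and 21840 ± 8844 (SD, n = 2). The inflammatory call was lost without control 4 weeks pool 1 (median 0.20, adjusted p = 0.641) or transgenic 4 weeks pool 2 (0.04, adjusted p = 0.634), and the median was 0.69 (adjusted p = 7.27e-06) without transgenic 4 weeks pool 1 and 0.71 (adjusted p = 1.08e-05) without control 4 weeks pool 2. With the actin ratio as a covariate the inflammatory median was 0.56 (adjusted p = 7.72e-05). It was 0.34 between the pools numbered 1 and 0.52 between those numbered 2. In these 3 lists 0 genes passed, adjusted over the list alone or over all genes.

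A further 6 lists passed in camera at 4 weeks, each losing the call with an estimated correlation and without at least 1 pool. Cell division genes had a median of 0.37, adjusted p = 0.00568, and adjusted p = 0.616 with an estimated correlation. Birc5, the mitotic protein survivin, was the 1 gene of 23 that passed adjusted over that list alone, with 163 ± 26.9 in control and 511 ± 58.5 (SD, n = 2) in transgenic pools, while Tpx2, a spindle protein of the same list, had a negative log2 difference of −1.94 (SE 0.70). The cell division median was 0.06 (adjusted p = 0.39) without control 4 weeks pool 2 and 0.09 (adjusted p = 0.227) without transgenic 4 weeks pool 1, and 0.63 and 0.55 without control 4 weeks pool 1 and transgenic 4 weeks pool 2. With the actin ratio as a covariate it was 0.06 (adjusted p = 0.391). CC chemokines had a median of 0.30, adjusted p = 0.0173, and adjusted p = 0.283 with an estimated correlation, 0.22 (adjusted p = 0.133) without control 4 weeks pool 1 0.07 (adjusted p = 0.292) without transgenic 4 weeks pool 2 and 0.68 (adjusted p = 0.00489) without transgenic 4 weeks pool 1. Ccl17, a chemokine for T cells, gave 282 ± 304 in control and 883 ± 238 (SD, n = 2) in transgenic pools. Eosinophil and mast cell genes had a median of 0.53, adjusted p = 0.0173, and adjusted p = 0.45 with an estimated correlation, 0.32 (adjusted p = 0.276) without control 4 weeks pool 1 and 0.15 (adjusted p = 0.242) without transgenic 4 weeks pool 1. Siglecf, a lectin of eosinophils, gave 309 ± 132 and 624 ± 101 (SD, n = 2). TGF-beta response genes had a median of 0.24, adjusted p = 0.0383, and adjusted p = 0.322 with an estimated correlation, 0.32 (adjusted p = 0.232) without control 4 weeks pool 1 and 0.10 (adjusted p = 0.547) without transgenic 4 weeks pool 2. The TGF-beta median was 0.50 without transgenic 4 weeks pool 1 and 0.37 without control 4 weeks pool 2, 0.43 (adjusted p = 0.0313) with the actin ratio as a covariate, and 0.21 (adjusted p = 0.051) after quantile normalization. Between the pools numbered 1 and those numbered 2 the medians were 0.27 and 0.39 for cell division genes, 0.28 and 0.30 for chemokines, 0.83 and 0.07 for eosinophil and mast cell genes and 0.12 and 0.47 for TGF-beta response genes.

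Fibroblast genes had a median of 0.34 at 4 weeks, adjusted p = 0.0491, and adjusted p = 0.651 with an estimated correlation. That median was 0.00347 (adjusted p = 0.548) without control 4 weeks pool 2, 0.00102 (adjusted p = 0.956) without transgenic 4 weeks pool 1, and 0.34 without transgenic 48 hours pool 1 (adjusted p = 0.053) or pool 2 (adjusted p = 0.0502). It was 0.63 (adjusted p = 0.000753) without transgenic 4 weeks pool 2, 0.30 between the pools numbered 1 and −0.04 between those numbered 2. The call was also lost with the actin ratio as a covariate (0.17, adjusted p = 0.315) and after quantile normalization (0.33, adjusted p = 0.0654). Luminal genes had a median of −0.15, adjusted p = 0.0399, and adjusted p = 0.515 with an estimated correlation, −0.25 (adjusted p = 0.276) without control 4 weeks pool 1 and 0.03 (adjusted p = 0.569) without transgenic 4 weeks pool 2. The luminal median was −0.48 (adjusted p = 0.00384) without transgenic 4 weeks pool 1, −0.51 (adjusted p = 0.0215) without control 4 weeks pool 2, −0.14 between the pools numbered 1 and −0.69 between those numbered 2. It was −0.45 (adjusted p = 0.0504) with the actin ratio as a covariate and −0.15 (adjusted p = 0.051) after quantile normalization. Krt19, a luminal keratin, gave 1174 ± 619 in control and 533 ± 314 (SD, n = 2) in transgenic pools. The luminal list stood at 0.39 and 0.31 above the mean of all arrays in the control 4 weeks pools and at 0.30 and −0.22 in the transgenic ones. In the fibroblast, luminal, chemokine, eosinophil and mast cell and TGF-beta lists 0 genes passed at 4 weeks, adjusted over the list alone or over all genes.

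Single genes at 4 weeks included Cx3cr1, the fractalkine receptor, at 540 ± 72.6 in control and 1909 ± 706 (SD, n = 2) in transgenic pools, a log2 difference of 1.72 (SE 0.29). The Cx3cr1 gene lies on chromosome 9 at 120048683 to 120068296. F5, coagulation factor V, gave 1236 ± 269 and 3294 ± 166 (SD, n = 2), and Serpinb2, an inhibitor of plasminogen activators, had a log2 difference of 2.39 (SE 0.53). Cd2, an adhesion receptor of T and NK cells, had 1.62 (SE 0.31), and Cd24a, a surface glycoprotein, 1.03 (SE 0.24). At 48 hours the mean signal of Cx3cr1 was 2744 in control and 1712 in transgenic pools, that of F5 6544 and 3761, and that of Serpinb2 3507 and 2193. For Cx3cr1, F5 and Serpinb2 the control 4 weeks pools were thus the lowest group. The transgenic means of F5 and Serpinb2 were not higher at 4 weeks than at 48 hours. The smallest p-values belonged to Dnajc17, a co-chaperone, at 2.65 (SE 0.38) and Pms2, a DNA mismatch repair protein, at −2.81 (SE 0.40), both with limma's adjusted p = 0.198, the lowest of the comparison. Both other kept probe sets of Pms2 had a difference of the opposite sign. Isg20, an interferon-induced exonuclease, had −1.82 (SE 0.41). Nrip2 gave 1351 ± 22.8 in control and 35880 ± 10400 (SD, n = 2) in transgenic pools, a log2 difference of 4.67 (SE 0.89), while its transgenic 48 hours pools alone spread over 21420 ± 26340, and its 1 other kept probe set had a difference of the opposite sign at 4 weeks. Of the 12 other kept probe sets of the genes named by their rank at 4 weeks, 6 had the same direction as the one used, and at 48 hours 7 of 11. In limma, 0 of 13083 genes passed at 4 weeks. At an unadjusted p under 0.05 there were 655 genes, 254 higher and 401 lower, against 654 by chance. With the pool number as a block Dnajc17 and Serpinb2 passed, with limma's adjusted p = 0.0246 each. Nrip2 passed over all genes with limma's adjusted p = 0.00235 with the 4 arrays of 4 weeks alone. Its log2 difference was 4.67 in that fit too, and without either transgenic 48 hours pool. Such fits change only the shared estimate of its spread, which the transgenic 48 hours pools widen.

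**Figure D4:**
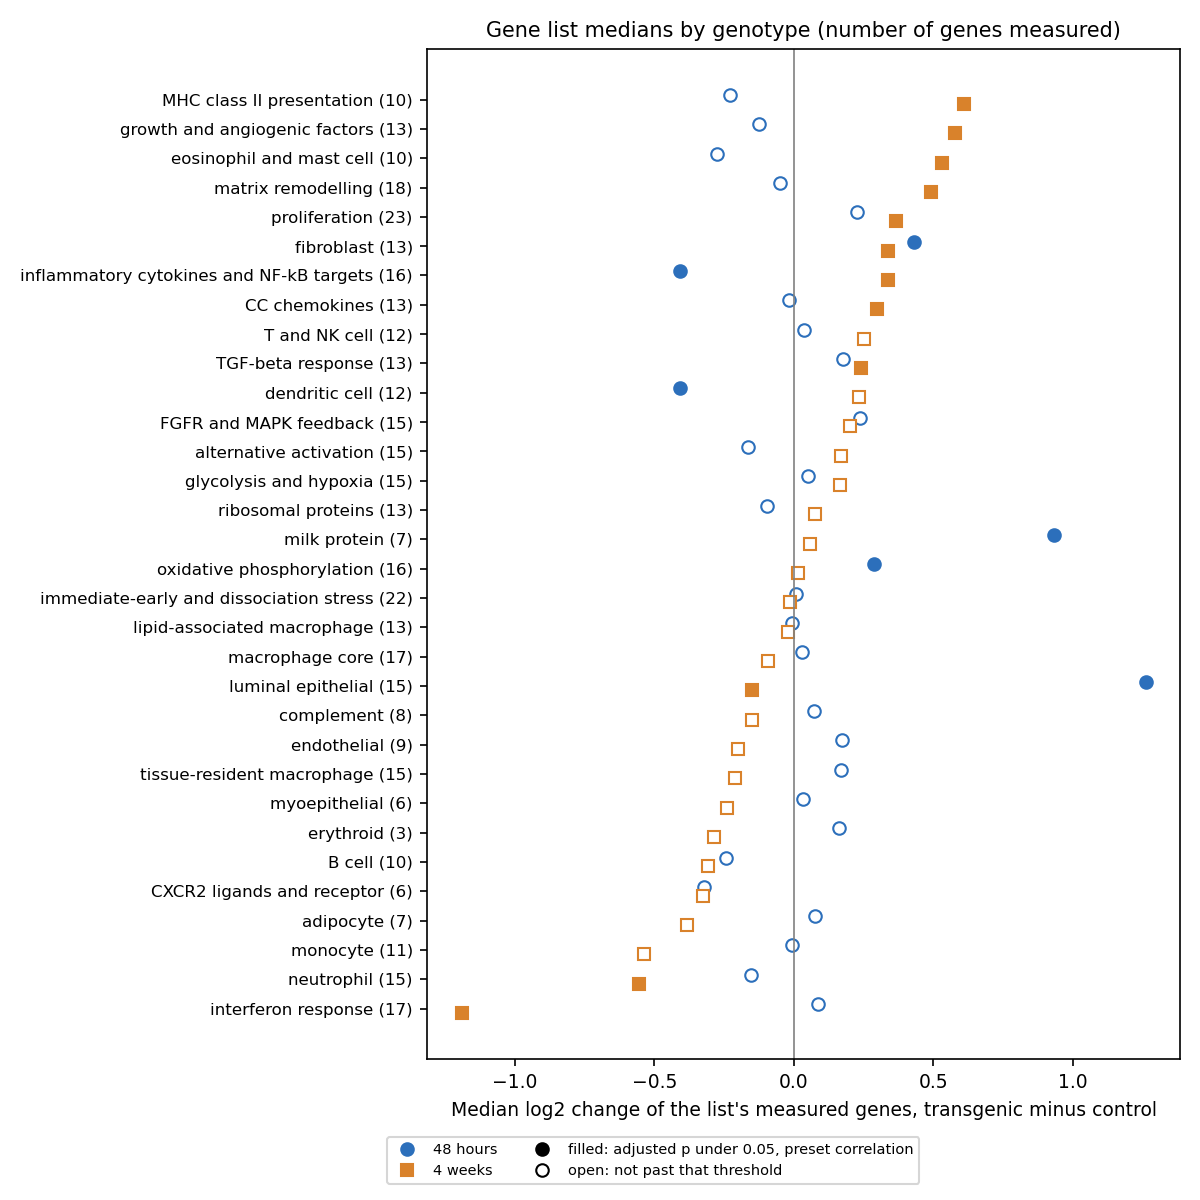
Median log2 difference, transgenic minus control, of each of the 32 gene lists at 48 hours and at 4 weeks (1 point per list and time on a log2 axis), filled where camera's adjusted p with the preset correlation was under 0.05. The luminal list stands at 1.26 at 48 hours and the interferon list at −1.19 at 4 weeks, and 0 lists passed with an estimated correlation.

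The interaction tested whether the genotype difference itself differed between the times. Luminal genes had a genotype difference lower at 4 weeks than at 48 hours, with a median of −1.50, adjusted p = 2e-08, and adjusted p = 0.306 with an estimated correlation. Of 15 luminal genes, 7 passed adjusted over the list alone and 0 over all genes, among them Krt8 at −2.80 (SE 0.50) and Krt19 at −3.11 (SE 0.63). Interferon genes had a median of −0.94, adjusted p = 1.32e-07, and adjusted p = 0.331 with an estimated correlation, and 1 of 17, Oas2 at −1.49 (SE 0.38), passed adjusted over the list alone. Inflammatory genes had the opposite sign with 16 of 16 positive and a median of 0.80, adjusted p = 2.14e-07, and adjusted p = 0.331 with an estimated correlation. Ptgs2 had an interaction of 1.43 (SE 0.46) and Il1b of 1.29 (SE 0.41). MHC class II genes had 10 of 10 positive and a median of 0.80, adjusted p = 3.83e-05, and adjusted p = 0.442 with an estimated correlation. Matrix remodelling genes had a median of 0.83, adjusted p = 0.00164, and adjusted p = 0.306 with an estimated correlation, with fry's adjusted p = 0.0194. Timp1, an inhibitor of matrix metalloproteases, had an interaction of 1.47 (SE 0.46). These 5 lists were called in each of the 8 fits without 1 pool. Without single pools the medians still moved: without control 48 hours pool 1 to 0.47 for inflammatory, 0.46 for MHC class II and 0.53 for matrix genes, without control 48 hours pool 2 to 1.24 for MHC class II and 0.54 for matrix genes, and without control 4 weeks pool 1 to 0.47 for inflammatory and 0.50 for MHC class II genes. Without control 4 weeks pool 2 they moved to −1.56 for interferon and 1.31 for inflammatory genes, and the inflammatory median was 1.24 and 0.41 without transgenic 4 weeks pools 1 and 2. Between the pools numbered 1 and those numbered 2 the medians were −1.22 and −1.58 for luminal, −1.46 and −0.67 for interferon, 1.10 and 0.72 for inflammatory, 0.89 and 0.74 for MHC class II and 0.43 and 0.61 for matrix genes. In limma, 0 of 13083 genes passed the interaction test, with 616 at an unadjusted p under 0.05 against 654 by chance and a lowest adjusted p of 0.19, for Zdhhc12.

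Across the 13083 genes, the log2 differences at the 2 times had a Pearson correlation of −0.00489 and a Spearman correlation of 0.00471, and 50.6% had the same sign. The Pearson correlation was 0.09 without control 4 weeks pool 1 and −0.10 without control 4 weeks pool 2. Genes are not independent, so no p-value was attached. At an unadjusted p under 0.05, 13 genes were higher at both times against 5.36 for independent tests, and 13 were lower at both against 7.94. A further 13 were higher at 48 hours and lower at 4 weeks against 8.46, and 17 the reverse against 5.03. The tests at the 2 times share each gene's estimate of spread and are not independent. Every count lay above its value, opposite directions included, so the counts do not show an overlap beyond chance.

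The genotype difference over both times compared the 4 transgenic with the 4 control pools. Neutrophil genes were lower, though Ltf and Lcn2 had higher signals in transgenic pools at 48 hours, with 14 of 15 negative and a median of −0.44, adjusted p = 0.000683, and adjusted p = 0.571 with an estimated correlation. S100a9 had a log2 difference of −1.41 (SE 0.31) and S100a8 of −1.49 (SE 0.33), and both passed adjusted over the list alone. Interferon genes had a median of −0.65, adjusted p = 2.5e-06, and adjusted p = 0.586 with an estimated correlation, with Rsad2 at −0.94 (SE 0.23) the 1 gene that passed adjusted over the list alone. Vegfa, at 1.45 (SE 0.37), was the 1 growth factor gene that did so, and Birc5, at 1.23 (SE 0.24), the 1 cell division gene. The medians between the pools numbered 1 and 2 were −0.18 and −0.63 for neutrophil and −0.61 and −0.51 for interferon genes. The neutrophil median was −0.26 without transgenic 48 hours pool 1 and −0.23 without control 4 weeks pool 2, and the interferon median −0.27 without control 4 weeks pool 1 and −0.43 without transgenic 4 weeks pool 2, all with adjusted p under the threshold. Of 32 lists, 7 passed with the preset correlation and 0 with an estimated one. In limma, 0 of 13083 genes passed, with 602 at an unadjusted p under 0.05 against 654 by chance and a lowest adjusted p of 0.366, for Krt78.

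The change over time in the controls compared pools that differ in age and length of dimerizer treatment, without the transgene. The genotype comparisons use the same control pools, so a change shared with them is not a separate observation. Luminal genes stood at −0.71 and −0.626 in the control 48 hours pools, and interferon genes at 1.13 in control 4 weeks pool 1. Age and dimerizer cannot be told apart from other differences between these pools. F5, coagulation factor V, fell from 6544 ± 1838 at 48 hours to 1236 ± 269 (SD, n = 2) at 4 weeks, a log2 change of −2.36 (SE 0.26), with limma's adjusted p = 0.0366, and both late pools lay below both early pools. The F5 gene lies on chromosome 1 at 164151835 to 164220277. It was the 1 gene of 13083 that passed, and 806 genes, 443 higher and 363 lower at 4 weeks, had an unadjusted p under 0.05 against 654 by chance. The F5 call was lost without control 48 hours pool 1 (adjusted p = 0.113) or pool 2 (0.115), control 4 weeks pool 1 (0.3), transgenic 48 hours pool 1 (0.0698) or pool 2 (0.0695), and transgenic 4 weeks pool 1 (0.0585) or pool 2 (0.0595), and the count was 7 genes without control 4 weeks pool 2 and 7 with the actin ratio as a covariate. F5 also missed the threshold with the filter at the 75th percentile (adjusted p = 0.0625), without the trend in the prior variance (0.193) and with array weights (0.0573). Cx3cr1 had a log2 difference of −2.28 (SE 0.29), with limma's adjusted p = 0.0869. Serpinb2 had one of −3.46 (SE 0.53) and Cd8a, a T cell and dendritic cell coreceptor, of −2.94 (SE 0.47), both with adjusted p = 0.216. With the pool number as a block limma's adjusted p was 0.00137 for Serpinb2, 0.0443 for Cd8a and 0.0443 for Cx3cr1.

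Luminal genes were higher in the later control pools, with 12 of 15 positive and a median log2 difference of 1.08, adjusted p = 2.1e-08, and adjusted p = 0.45 with an estimated correlation. Krt8 had a difference of 2.09 (SE 0.35) and Krt19 of 2.21 (SE 0.44), and 8 of 15 genes passed adjusted over the list alone while 0 passed over all genes. The luminal median was 1.13 between the pools numbered 1 and 0.81 between those numbered 2. Interferon genes were higher by a median of 0.73, adjusted p = 7.01e-06, and adjusted p = 0.516 with an estimated correlation. Without control 4 weeks pool 1 the interferon median was 0.43 (adjusted p = 0.171), without control 4 weeks pool 2 it was 1.17 (adjusted p = 4.67e-10), and it was 1.51 between the pools numbered 1 and 0.07 between those numbered 2. Inflammatory genes were lower by a median of −0.51, adjusted p = 5.02e-05, and adjusted p = 0.516 with an estimated correlation. Without control 4 weeks pool 1 the inflammatory median was −0.23 (adjusted p = 0.231), without control 48 hours pool 1 it was −0.26 (adjusted p = 0.0378) and without control 4 weeks pool 2 −0.88 (adjusted p = 8.79e-07). It was −0.99 between the pools numbered 1 and −0.04 between those numbered 2. Eosinophil and mast cell genes were lower by −0.61, adjusted p = 0.00131, and adjusted p = 0.45 with an estimated correlation, with Siglecf at −2.03 (SE 0.34) and Ccr3, the eotaxin receptor, at −2.33 (SE 0.64) among the 3 of 10 that passed adjusted over the list alone. That call was lost without control 48 hours pool 2 (median −0.56, adjusted p = 0.0767), and the median was −1.01 without control 48 hours pool 1, −0.22 without control 4 weeks pool 1 and −0.999 without control 4 weeks pool 2. It was −1.04 between the pools numbered 1 and −0.52 between those numbered 2.

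**Figure D5:**
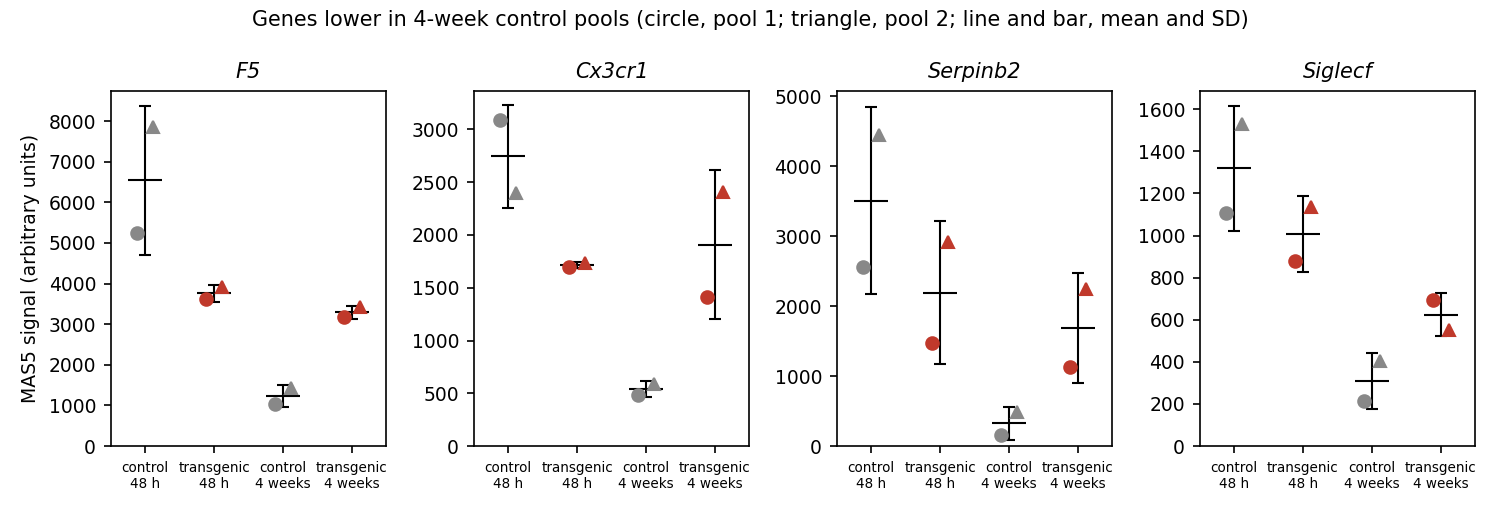
MAS5 signal (linear axis from 0) of F5, Cx3cr1, Serpinb2 and Siglecf in the 4 groups, with circles for pool 1, triangles for pool 2, grey for control and red for transgenic pools, and a line and bar for the mean and SD of 2 pools. The control 4 weeks pools are the lowest group for each gene, as for F5 with a mean of 1236 against 6544 in the control 48 hours pools.

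In the transgenic pools, matrix remodelling genes were higher at 4 weeks than at 48 hours, with 16 of 18 positive and a median of 0.46, adjusted p = 2.72e-05, and adjusted p = 0.212 with an estimated correlation. Fry gave the list an adjusted p = 0.0143, and Mmp12 had a log2 difference of 1.12 (SE 0.38) and Fn1 of 0.56 (SE 0.24). MHC class II genes had 10 of 10 positive and a median of 0.60, adjusted p = 5.29e-07, and adjusted p = 0.715 with an estimated correlation. H2-Ab1, a class II beta chain, had a difference of 0.71 (SE 0.32), and the call was lost without transgenic 4 weeks pool 2 (median 0.41, adjusted p = 0.0595). The class II median was 0.91 without transgenic 48 hours pool 1 and 0.91 without transgenic 4 weeks pool 1. Between the pools numbered 1 and those numbered 2 the medians were 0.20 and 0.62 for matrix and 0.15 and 1.12 for MHC class II genes. In both lists 0 genes passed, adjusted over the list alone or over all genes. In limma, 0 of 13083 genes passed, and 285, 150 higher and 135 lower, had an unadjusted p under 0.05 against 654 by chance.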

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

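The tests of epithelial cells in the sorted fraction, of a lower share of macrophages, of the interferon genes without control 4 weeks pool 2, and of the spike-in and hybridisation controls were chosen only after the results were seen. The actin ratio as a covariate was an alternative added after seeing the data.

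Luminal epithelial genes stood higher in transgenic pools at 48 hours by a median of 1.26, and the genotype difference was lower at 4 weeks than at 48 hours by a median of −1.5, adjusted p = 2e-08, with adjusted p = 0.516 for the first and 0.306 for the other with an estimated correlation. With each array's actin ratio as a covariate the 48 hours median was 1.14, adjusted p = 6.28e-09 in camera. That fit rests chiefly on control 4 weeks pools 1 and 2, at log2 ratios of 2.998 and 5.211, with the luminal list at 0.39 and 0.306. It argues against RNA degradation as the whole cause only as far as those pools show. A lower share of macrophages that raises all other cell types alike was weighed on 44 leukocyte genes. These genes of T and NK, B, dendritic, eosinophil and mast cells had a median of −0.215 (95% bootstrap interval over genes −0.38 to −0.0355). NK cells and some dendritic cells carry Cd11b and are sorted with macrophages, so these genes cannot decide it. The 22 of T and NK and B cells alone had −0.132 (−0.357 to 0.0441), against 0.171 to 1.95 for the luminal list. This argues against such a rise in those cells, though NK genes are among them. The macrophage core median was 0.0308. Pooled, 35 fibroblast, endothelial, adipocyte and myoepithelial genes went the luminal way, with a median of 0.307 (0.116 to 0.413). The median was 0.431 for fibroblast, 0.172 (−0.0687 to 0.428) for endothelial, 0.0762 for adipocyte and 0.0325 for myoepithelial genes. Of these lists camera called only the fibroblast one, whose median turned to −0.11 without control 48 hours pool 1. A larger share of epithelial and stromal cells together was not excluded, and these intervals leave out the spread between pools. Epithelial cells or their RNA carried into the sorted fraction, which staining for Cd11b should remove, may differ between pools: 12 of 15 luminal genes were higher, with signals of 3219 for Krt8, 6573 for Csn3 and 5522 for Wfdc18, but the mean correlation between luminal genes over the 8 arrays, 0.289, lay between the bounds set for and against it. The 2 control 48 hours pools had the lowest luminal signal of the 8 arrays, so the difference at 48 hours cannot be told apart from a low carry-over in those pools. A response of the gland to the activated receptor stays open and was not tested.

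Interferon response genes stood lower in transgenic pools at 4 weeks by a median of −1.19, and their genotype difference was lower at 4 weeks than at 48 hours by −0.943, adjusted p = 1.32e-07, and adjusted p = 0.331 with an estimated correlation. The RNA quality of control 4 weeks pool 2, read from its high 3' to 5' ratios, was argued against as the cause. Without that pool, with pool 1 as the only 4 weeks control, the median was −1.62. With the actin ratio as a covariate the median was −1.48, adjusted p = 4.64e-16 in camera. That covariate is fitted from differences within groups, chiefly between control 4 weeks pools 1 and 2, at log2 ratios of 2.998 and 5.211. It thus largely repeats leaving out pool 2 and cannot decide on RNA degradation over all arrays. Control 4 weeks pool 1 stood 1.13 above the mean of all arrays in these genes and may carry part of the difference: without it the median was −0.731. The only 4 weeks control was then pool 2, with its high actin ratio. With an estimated correlation between genes the list at 4 weeks had adjusted p = 0.283. An effect of the transgene on the macrophages stays open and was not tested.

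Compared with the arrays of the other groups alone, leaving out the pool of the same group, each of the 8 arrays was most similar to an array of its own pool number. A round of sample preparation shared by the pools of one number may be behind this: the mean log2 signal of the spike-in RNAs added before amplification was 0.3798 higher on the arrays of pools 2, exact permutation p = 0.02857, the smallest that 4 against 4 arrays can give. A shared round of hybridisation stays open: the controls added at that step differed by 0.07757 (95% interval −0.2163 to 0.3714), exact permutation p = 0.5714, too few arrays to decide, and such a round need not shift these controls. The labels give no dates, and no biological explanation was tested.

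For the genotype difference over both times, chance cannot be excluded for the count at an unadjusted p under 0.05: the real split gave 602 genes in limma, 14 of the 34 splits of the 8 arrays that could be fitted gave as many or more, and the highest of the others gave 1384, against 1096 for the split by pool number. The count past adjusted p of 0.05 decides nothing about chance, since the real split gave 0 genes and 34 of 34 splits had to give as many. The highest of the others was 5, for the split that parts the pools numbered 1 from those numbered 2. With the pool number as a block the real count was 0, with 662 genes at an unadjusted p under 0.05.

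Control 4 weeks pool 2 stood apart from the other 7 arrays in 3 of the ratios of RNA quality, at a log2 ratio of 5.211 for actin 3' to 5', 3.592 for Gapdh 3' to 5' and 2.391 for actin 3' to the middle. Chance alone sets apart about 1 in 20 groups by this measure, and the 3 ratios come from the same array and are not independent.

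In 3 further lists the genotype difference itself differed between the times in each of the 8 fits without 1 pool, as a median of the difference at 4 weeks minus that at 48 hours. The median was 0.802 for inflammatory cytokines and NF-kB targets, adjusted p = 2.14e-07, and adjusted p = 0.331 with an estimated correlation. For MHC class II presentation it was 0.799, adjusted p = 3.83e-05, and adjusted p = 0.442 with an estimated correlation. For matrix remodelling it was 0.828, adjusted p = 0.00164, and adjusted p = 0.306 with an estimated correlation. Without single pools the medians ran from 0.412 to 1.31 for inflammatory and from 0.464 to 1.24 for MHC class II genes, and the lowest for matrix genes was 0.534. The lowest were without transgenic 4 weeks pool 2 for inflammatory and without control 48 hours pool 1 for the other lists, and the highest without control 4 weeks pool 2 for inflammatory and control 48 hours pool 2 for MHC class II genes.

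In 8 other lists the difference between the times passed with all arrays at the preset correlation and was lost without some pools, and with an estimated correlation their adjusted p ran from 0.331 to 0.587. Tissue-resident macrophage genes had −0.363 (adjusted p = 0.0215), −0.288 without transgenic 48 hours pool 1, −0.369 without control 48 hours pool 2, 0.00616 and −0.66 without control 4 weeks pools 1 and 2 and −0.242 without transgenic 4 weeks pool 2, and −0.573 with the actin ratio as a covariate. Dendritic cell genes had 0.426 (adjusted p = 0.00314), 0.306 and 0.772 without control 4 weeks pools 1 and 2 and 0.436 without transgenic 4 weeks pool 2. Eosinophil and mast cell genes had 0.739 (adjusted p = 0.00314), 0.504 and 1.23 without control 4 weeks pools 1 and 2 and 0.596 without control 48 hours pool 2. Milk protein genes had −1.46 (adjusted p = 0.0364), −0.685 without control 48 hours pool 1, −1.37 without transgenic 48 hours pool 1, −1.56 without transgenic 48 hours pool 2, 0.284 and −2.77 without control 4 weeks pools 1 and 2 and −0.634 without transgenic 4 weeks pool 2. CC chemokines had 0.511 (adjusted p = 0.0281), 0.316 and 0.86 without control 48 hours pools 1 and 2, 0.373 without transgenic 48 hours pool 2, 0.193 and 0.331 without control 4 weeks pools 1 and 2 and 0.34 without transgenic 4 weeks pool 2. Growth and angiogenic factors had 0.497 (adjusted p = 0.0139), 0.254 and 0.788 without transgenic 48 hours pools 1 and 2, 0.14 and 0.819 without control 4 weeks pools 1 and 2 and 0.994 and 0.248 without transgenic 4 weeks pools 1 and 2. Oxidative phosphorylation genes had −0.263 (adjusted p = 0.03), −0.209 and −0.146 without control and transgenic 48 hours pool 1, −0.231 without control 4 weeks pool 1 and −0.202 without transgenic 4 weeks pool 2. Ribosomal protein genes had 0.182 (adjusted p = 0.0364), 0.0993 without control 48 hours pool 1, 0.081 without transgenic 48 hours pool 2, 0.182 and 0.158 without control 4 weeks pools 1 and 2 and 0.12 without transgenic 4 weeks pool 2, and its call was also lost at 0.161 under quantile normalization (adjusted p = 0.0582) and with the actin ratio as a covariate (adjusted p = 0.0984). With an estimated correlation 0 of the 13 lists that differed between the times were called.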

How the results depend on the processing

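The actin ratio as a covariate and, for the correlation between the genotype differences, the leaving out of pools and the replicate block were chosen after seeing the data; the other alternatives were planned.

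In limma, the genotype comparisons kept 0 genes past adjusted p of 0.05 under quantile normalization, both offsets, both filters, all probe sets, no trend, array weights, adjusted p of 0.10 and a 2-fold minimum. At 48 hours the unadjusted counts under p of 0.05 were 534 with quantile normalization and 512 without an offset, and at 4 weeks 669 and 623. The counts became 1 at 48 hours and 1 at 4 weeks when the 4 arrays of that time were fitted alone. Leaving out 1 pool gave 0 to 1 genes for each genotype comparison, for the interaction and for time in transgenics, and 0 to 7 for time in controls, with 7 without control 4 weeks pool 2. The 1 gene changed over time in controls, F5, became 0 genes with the filter at the 75th percentile (adjusted p = 0.0625), without the trend (0.193) and with array weights (0.0573); the count was 2 at adjusted p of 0.10, a looser threshold. With the actin ratio as a covariate 7 genes and 12 lists were called over time in controls, and 0 genes in the other comparisons of group means. Of the lists, 0 were called with an estimated correlation in each of the 6 comparisons. With fry, 0 were called at 48 hours, 1 at 4 weeks, 1 for the interaction, 0 over both times, 0 over time in controls and 1 over time in transgenics. Quantile normalization called 9 lists at 4 weeks against 12, without the luminal (adjusted p = 0.051), fibroblast (0.0654) and TGF-beta (0.051) lists, and 12 for the interaction against 13, without the ribosomal one (0.0582). Leaving out 1 pool gave 4 to 9 lists at 48 hours, 7 to 14 at 4 weeks, 7 to 14 for the interaction, 5 to 11 over both times, 6 to 14 over time in controls and 1 to 9 over time in transgenics. The correlation between the genotype differences ran from −0.105 without control 4 weeks pool 2 to 0.0898 without control 4 weeks pool 1. Apart from the alternatives with fewer arrays, the cause was not tested.

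With the replicate block, the pool number as a covariate, the count was 2 at 4 weeks (Dnajc17 and Serpinb2, adjusted p = 0.0246 each) and 4 over time in controls, where Serpinb2 (0.00137), Cd8a (0.0443) and Cx3cr1 (0.0443) joined F5; 0 genes passed in the other comparisons. The fibroblast list at 4 weeks (adjusted p = 0.0561) and the luminal list over both times (0.0605) were not called with the block, no other called list lost its call, and the cause was not tested. The labels do not say what pools of one number share. The correlation of their deviations between groups ran from −0.0845 to 0.133 and was over 0.1 in 3 of 6 pairs of groups, so they were not treated as paired, although among the arrays of other groups each of the 8 was closest to an array of its own number. Of all arrays, control 48 hours pool 1 was closest to pool 2 of its own group.

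Direction turned in 4 list medians and 1 gene, each without 1 pool. The fibroblast median at 48 hours ran from −0.11 without control 48 hours pool 1 to 0.94 without control 48 hours pool 2, and the Fgfr1 difference at 4 weeks from −0.53 without control 4 weeks pool 2 to 1.10 without control 4 weeks pool 1. The luminal median at 4 weeks ran from −0.508 without control 4 weeks pool 2 to 0.0278 without transgenic 4 weeks pool 2. For the interaction, tissue-resident macrophage genes ran from −0.66 without control 4 weeks pool 2 to 0.00616 without pool 1, and milk protein genes from −2.77 to 0.284 without the same pools; the cause was not tested. Over the named genes and alternatives, 2439 values stayed on their side of the threshold, 12 came to pass it and 10 no longer did. Only F5 had passed in the main fits, so nearly all values that stayed had not passed before, and the 10 losses were all of F5. Over the called lists, 450 stayed and 189 lost the call in the same direction. These totals do not measure how well the lists hold. With an estimated correlation 50 lost the call, and with fry 47 lost it and 3 kept it. Fits without 1 pool kept 316 calls, but many left out a pool outside the contrast, which cannot move a list's median. The pool number as a block cannot move it either. With the actin covariate 4 of 6 lists called at 48 hours were still called, without the milk protein and dendritic lists, and 9 of 12 at 4 weeks, without the luminal, fibroblast and cell division lists. At 4 weeks 5 lists came to be called, 14 in all: macrophage core (−0.276), tissue-resident macrophage (−0.336), dendritic cell (0.221, adjusted p = 0.0121), complement (−0.577, adjusted p = 3.24e-05) and milk protein (−1.8, adjusted p = 0.0118), whose median without the covariate was 0.0575. For the interaction 12 of 13 were still called and complement was added (−0.471), and over time in transgenics 6 of 6 were and neutrophil was added (−0.362). Over time in controls 6 of 6 were, and tissue-resident macrophage, dendritic, milk protein, CC chemokine, complement and oxidative phosphorylation were added. The covariate is fitted from differences within groups, chiefly between control 4 weeks pools 1 and 2, at log2 ratios of 2.998 and 5.211. Relative to the mean of all arrays, milk protein genes stood at 1.4 and −1.05 in those pools and complement genes at 0.595 and −0.212. The added calls thus do not show changes corrected for RNA quality over all arrays. Dim genes carry signals near the offset of 30.8, where log2 differences are compressed and background is a large part of the signal.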

Other observations

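No test of a hypothesis was added here; apart from the actin ratio as a covariate, the values below come from the planned tests. Of 17 macrophage core genes, 9 had a positive genotype difference at 48 hours with a median of 0.03, adjusted p = 0.397 in camera, where the mean of −0.02 and the test had the opposite sign. At 4 weeks 6 were positive with a median of −0.09 and a mean of 0.07, adjusted p = 0.996. With the actin ratio as a covariate, chosen after seeing the data, the macrophage core median at 4 weeks was −0.28 (adjusted p = 0.0223), and that of tissue-resident macrophage genes −0.34 (adjusted p = 1.06e-05) against −0.21 (adjusted p = 0.119) without the covariate. That covariate rests chiefly on control 4 weeks pools 1 and 2, where the macrophage core list stood at 0.227 and −0.232. It cannot decide on RNA quality over all arrays. Cxcl1 and Cxcl2, neutrophil-attracting chemokines, were among the bright genes on all arrays, with Cxcl1 at 56396 to 87688 and Cxcl2 at 54300 to 81577. The list of CXCR2 ligands and their receptor had a median of −0.32 at 48 hours, adjusted p = 0.314, and −0.33 at 4 weeks, adjusted p = 0.489. Genes of FGFR and MAPK feedback had 12 of 15 positive at each time, with medians of 0.24, adjusted p = 0.364, and 0.20, adjusted p = 0.133. Immediate-early and dissociation stress genes, which respond to tissue digestion, had medians of 0.01, adjusted p = 0.814, and −0.01, adjusted p = 0.499, and their means of 0.02 and 0.05 and the test differed in sign from each other or from the median. Myoepithelial genes, the other layer of the mammary epithelium, had a median of 0.03 at 48 hours, adjusted p = 0.777, with 3 of 6 positive.

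In the control pools, T and NK cell genes were lower at 4 weeks than at 48 hours by a median of −0.48, adjusted p = 0.0102, and adjusted p = 0.45 with an estimated correlation, with Cd8a the 1 gene that passed adjusted over the list alone and 0 over all genes. The call was lost without control 48 hours pool 2 (median −0.84, adjusted p = 0.0767) or control 4 weeks pool 2 (−0.49, adjusted p = 0.12), and the median was −0.73 (adjusted p = 0.0149) without control 4 weeks pool 1. Growth and angiogenic factors were lower by −0.49, adjusted p = 0.00603, and adjusted p = 0.45 with an estimated correlation, −0.16 (adjusted p = 0.4) without control 4 weeks pool 1, −0.81 without control 4 weeks pool 2 and −0.80 without control 48 hours pool 2. None of these genes passed adjusted over the list alone.

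In the transgenic pools, dendritic cell genes were higher at 4 weeks than at 48 hours by a median of 0.27, adjusted p = 0.00422, and adjusted p = 0.715 with an estimated correlation, 0.20 (adjusted p = 0.183) without transgenic 48 hours pool 2 and 0.38 (adjusted p = 0.417) without transgenic 4 weeks pool 2. Itgax, which encodes the integrin Cd11c, gave 827 ± 19.0 at 48 hours and 1804 ± 510 (SD, n = 2) at 4 weeks. Inflammatory genes had a median of 0.27, adjusted p = 0.00185, and adjusted p = 0.822 with an estimated correlation, 0.41 (adjusted p = 0.092) without transgenic 48 hours pool 2 and 0.11 (adjusted p = 0.92) without transgenic 4 weeks pool 2. Interferon genes had a median of −0.34, adjusted p = 0.00422, and adjusted p = 0.822 with an estimated correlation, −0.26 (adjusted p = 0.183) and −0.15 (adjusted p = 0.192) without those pools. Luminal genes had a median of −0.43, adjusted p = 0.0157, and adjusted p = 0.757 with an estimated correlation, −0.24 (adjusted p = 0.303) and −0.13 (adjusted p = 0.834) without those pools. The call also held without the pools numbered 1, with medians of 0.52 for dendritic genes without transgenic 48 hours pool 1, and of 0.76 for inflammatory, −0.62 for interferon and −0.78 for luminal genes without transgenic 4 weeks pool 1. In these 4 lists 0 genes passed, adjusted over the list alone or over all genes.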
